A study of Mus musculus with 4 samples.

How the data were processed

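The series holds 4 samples of C2C12 cells, 2 stimulated with TGFb1 for 1 h and 2 for 6 h. According to the series' design text, these come from 2 independent experiments. Replicate numbers follow the order of deposition, and nothing in the labels pairs a sample at 1 h with one at 6 h. The deposited value is 1 score per well, a Smad4 localization measure near 1, per the labels' statement that fixed cells were analysed for Smad4 localization. How images were segmented, what the score is made of, its direction and any normalization are not given in the sources used here, nor is the number of cells behind it. The files have no header. Their first column repeats the positions A01 to P24 in 51 blocks, which were taken as plates and numbered in file order, and the second holds the score. A score of 0 or not a number was taken as no measurement (10 zeros and 1 not a number over the 4 samples). Plate medians differ within each file, so the scores as deposited are not centred per plate.

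The files pair wells with neither genes nor siRNAs, so the analysis planned for genes was run on wells, each with 1 value per sample. Tests of gene lists, values of the control targets TGFbR1 and XpoI, averaging of several values of a gene, and scaling to sensory receptor genes need gene names and were not run. Columns 1 to 22 are treated apart from columns 23 and 24, a division made after position means were seen.

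Scores were brought to a robust z score in each sample, by subtracting the sample's median and dividing by its scaled median absolute deviation. Wells with a score in all 4 samples (19573) were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with time as the group and all samples in 1 fit. The fit had 2 residual degrees of freedom and 6.03 prior degrees of freedom. A well was called shifted at a time when its mean z differed from 0, two-sided, with a Benjamini-Hochberg adjusted p under 0.05 and a size of at least 1. It was called different between times at an adjusted p under 0.05 for 6 h minus 1 h. A z score is relative to the sample, so the contrast is a change of place among wells. Wells beyond 2 in both replicates were set against 10000 permutations of well order, and correlations against 100000. The chance overlap of lists is the product of their sizes over the number of wells tested. Wells are named by a rule fixed before the data were examined, the highest and lowest mean z among called wells whose replicates both lie at least 1 on that side, and for the contrast the largest differences among called wells. Since the files pair no names with wells, only 2 wells per direction are named, and these were taken from columns 1 to 22. Position means over plates were fitted with limma in the same way over all positions of the plate. That fit has its own prior degrees of freedom, which are not given here.

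In simulated data for 19573 wells, the fit recovered 97% of wells shifted by 1.5 z and 100% of those shifted by 3 z at 1 h. For a difference between times it recovered 54% at 1.5 z and 99% at 3 z. Among unchanged wells, 15 were called at 1 h and 14 between times. The simulation drew independent normal noise with each well's fitted SD and changed 100 wells per size. It held no plate, edge or single-sample effects and far fewer changed wells than were called in the data, so recovery in the data may differ.

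Alternatives fixed before the data were examined were 1 common scale for all samples, normal scores of the ranks, subtraction of a running median in file order, log2 of the scores, eBayes with trend and robust options, samples of 1 time alone, other thresholds, wells with missing values, and leaving out each sample. Alternatives added after the data were seen were subtraction of the plate median over columns 1 to 22, scaling by each plate's own spread, removal of row and column medians within plates, columns 1 to 22 alone, and leaving out the 7 plates with a replicate correlation under 0.6 at either time. Statistics used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.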

Results

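The screen measured where Smad4, the shared partner of the receptor-activated Smads, was found in C2C12 cells, a mouse myoblast line that carried GFP fused to Smad4 and RFP fused to histone H2B. Each gene was knocked down with a pool of 3 siRNAs, TGFb1 at 2 ng/ml followed 48 h later, and cells were fixed after 1 h or 6 h of stimulation. The question was which genes change the movement of Smad4 into the nucleus, early and late. There were 4 samples, 2 per time. Each held 51 plates of 16 rows and 24 columns, or 19584 wells, with 1 Smad4 localization score per well. The definition of the score, and whether a higher score means more Smad4 in the nucleus, are not given in the sources used here, so scores are described only as higher or lower. The number of cells and images behind a score is not given either, so the depth of each value is unknown. The files pair no well with a gene or an siRNA, so items are plates and wells, numbered in file order. Values for the control targets, for Smad4 and for gene families were therefore not analysed here. Columns 1 to 22 of all plates make 17952 wells, 370 more than the 17582 genes stated for the screen.

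Overall scores were lower at 6 h than at 1 h. The median score was 1.151 and 1.148 in the samples at 1 h, and 1.024 and 1.022 at 6 h. The SD over all wells was 0.0503 and 0.0498 at 1 h and 0.0614 and 0.0601 at 6 h. A score was missing in 1 well of replicate 1 at 1 h, in 3 wells of replicate 1 at 6 h and in 7 wells of replicate 2 at 6 h. No test was applied to the overall level. The smallest two-sided p that an exact permutation test of 2 samples against 2 can give is 0.333. Plate by plate the direction was the same throughout. Plates are parts of the same 4 samples, and cells fixed at the 2 times are different cells. Here and below, counts of plates and SDs over plates therefore do not replicate the comparison of times. They also do not separate time from other differences between the samples. The median of columns 1 to 22 was lower at 6 h on 51 of 51 plates, by a mean difference (6 h minus 1 h) of -0.126 ± 0.0256 (SD over plates) and a range of -0.185 to -0.0778.

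**Figure D1:**
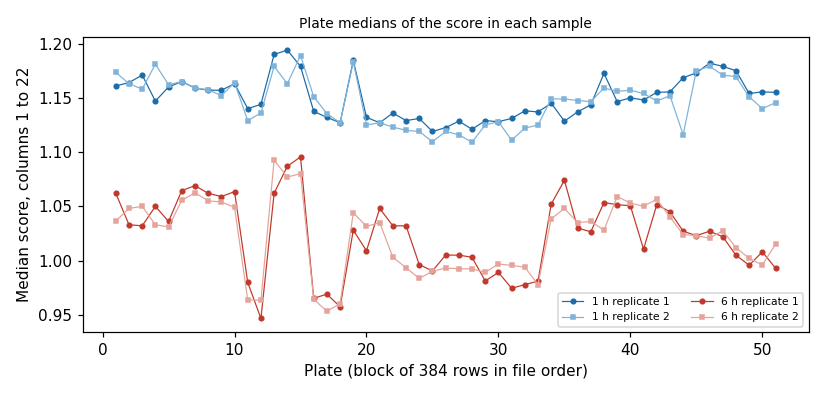
Median score of columns 1 to 22 (vertical axis, score) on each of the 51 plates in file order (horizontal axis), with 1 line per sample. Both samples at 6 h lie below both samples at 1 h on every plate, and plate medians at 6 h range from 0.955 to 1.09 as means of the replicates.

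Plate medians varied together between replicates. Across the 51 plates, the medians of the replicates at 1 h had a Pearson r of 0.815 and a Spearman rho of 0.828, and those at 6 h an r of 0.895 and a rho of 0.879. Means of the replicates at 1 h and at 6 h were related with an r of 0.653 and a rho of 0.653. Each of these coefficients had a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give, and 1e-05 after Benjamini-Hochberg adjustment over the 3 relations. Without the 2 plates farthest from the median, r was 0.820, 0.879 and 0.642. The plate medians had an SD of 0.0197 at 1 h and 0.0336 at 6 h. A plate carries the same wells in every sample, so these relations do not separate the handling of a plate from its contents. Results within plates, taken after subtracting each plate's median over columns 1 to 22, are given beside those from the scores as deposited.

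Replicates were compared across wells, which are not independent replicates. At 1 h, the Pearson correlation of the samples was 0.873 and Spearman's rho 0.848 over 19583 wells. At 6 h they were 0.851 and 0.845 over 19574 wells. Each coefficient had a two-sided permutation p of 1e-05 over 100000 permutations of well order, the smallest possible. Samples of different times correlated less, with r from 0.638 to 0.680. Within plates and over columns 1 to 22, r was 0.863 between replicates at 1 h and 0.772 at 6 h, and from 0.665 to 0.674 between samples of different times. The mean covariance between times, divided by the geometric mean of the covariances between replicates, gave a correlation between times of 0.820 corrected for replicate noise. The order of plates was the same in all files. In 612 of 612 comparisons of a plate with the 51 plates of another sample, the highest rank correlation over columns 1 to 22 was with the plate of the same number.

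Wells with a robust z score beyond 2 on the same side in both replicates were counted as a hit rule for a screen with 2 replicates. At 1 h, 941 of 19573 wells met it, 162 higher and 779 lower, where 10000 permutations of well order gave a mean of 60.6 and at most 91. At 6 h, 487 wells met it, 273 higher and 214 lower, where permutations gave a mean of 20.2 and at most 38. Both permutation p-values, one-sided, were 0.0001, the smallest possible. Within plates, the counts rose to 1358 wells at 1 h, 290 higher and 1068 lower, and to 1079 wells at 6 h, 458 higher and 621 lower. The mean count from permutations rose as well, to 116 at 1 h and 79.7 at 6 h. With 1 common scale for all samples, the deposited scores gave 662 wells at 1 h and 759 at 6 h. Which time had more wells beyond 2 thus depends on the scale. As deposited, columns 23 and 24 held 119 of the 162 higher wells at 1 h and 146 of the 273 at 6 h. Within plates and over columns 1 to 22 alone, 123 wells were higher and 1003 lower at 1 h, and 290 were higher and 580 lower at 6 h. Of these, 54 were higher at both times in all 4 samples, against 1.99 for independent lists, and 394 were lower, against 32.4. No well was beyond 2 on opposite sides at the 2 times, against 3.98 and 16.2 for independent lists. The mean z lay on the same side of 0 at the other time in 98.8% of the 1126 wells beyond 2 at 1 h and in 97.1% of the 870 at 6 h.

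A limma fit over the 4 samples tested each well's mean z at each time against 0, the median of its sample. At 1 h, 5879 of 19573 wells passed an adjusted p under 0.05 with a mean z of at least 1 in size, 2648 higher and 3231 lower. At 6 h, 5818 passed, 2787 higher and 3031 lower. These counts were set by the size threshold more than by the test, since 5914 wells at 1 h and 5869 at 6 h had a mean z of at least 1 in size. With a mean z of at least 2 in size, 1251 wells passed at 1 h, of which 995 were lower, and 727 at 6 h, of which 340 were lower. Within plates, 6125 wells passed at 1 h and 5916 at 6 h at a size of 1. Of the wells that passed at 1 h, 1240 were higher and 1564 lower at 6 h also, where independent lists would share 377 and 500. Within plates these overlaps were 1272 higher and 2095 lower, against 380 and 551. Only 32 wells passed on opposite sides at the 2 times, in either form of the values.

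The wells that headed the ranking were in large part at fixed positions of columns 23 and 24, which held 10 of the 10 highest at 1 h and 10 of the 10 highest at 6 h. They also held 2 of the 10 lowest at each time. Within columns 1 to 22, a restriction made after the values were seen, the lowest at 1 h were plate 2 well C07 and plate 28 well P01. Plate 2 well C07 had scores of 0.859 and 0.892, a mean z of -6.63 ± 0.279 (SE) and a limma adjusted p of 7.91e-06. It was low at 6 h too, with scores of 0.892 and 0.876. Plate 28 well P01 had a mean z at 1 h of -6.08 ± 0.386 (SE) with an adjusted p of 3.28e-05. The highest at 1 h were plate 8 well P08, with a mean z of 3.27 ± 0.738 (SE), and plate 4 well O22, with 2.80 ± 0.209 (SE). Their adjusted p-values were 0.00772 and 5.99e-05. The replicates of plate 8 well P08 differed widely, with z scores of 5.27 and 1.26, so that its z without replicate 1 was 1.26. All 4 kept their side within plates, with adjusted p-values from 3.26e-05 to 0.0199.

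At 6 h the lowest wells by the same rule, plate 25 well F21 and plate 25 well H20, rested on 1 replicate. Their scores were 0.957 and 0.962 in replicate 1, and 0.378 and 0.437 in replicate 2. Their mean z was -6.66 ± 1.92 (SE) and -6.06 ± 1.75 (SE), with limma adjusted p-values of 0.0215 and 0.0215 as deposited, and of 0.0513 and 0.0527 within plates. Without replicate 2 their z was -1.24 and -1.14. Both lie close to the 6 wells of plate 25 that have no score in that sample, in rows D to H and columns 19 to 22. The SD over columns 1 to 22 of plate 25 was 0.0808 in that sample, against a median of 0.0408 on its other plates. The highest were plate 51 well H05, with scores of 1.63 and 1.10 and a mean z of 6.40 ± 1.73 (SE), and plate 13 well O16, with scores of 1.28 and 1.18 and a mean z of 3.80 ± 0.442 (SE). Their adjusted p-values were 0.0166 and 0.000710. Plate 51 well H05 also rested on 1 replicate, with a z of 1.54 without replicate 1, and its adjusted p was 0.0681 after row and column medians were removed.

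The contrast of times asked which wells changed their place among all wells between 1 h and 6 h. It does not address the fall of the overall level, which scaling within each sample removes. As deposited, 2545 of 19573 wells differed at an adjusted p under 0.05 in limma, 1433 higher and 1112 lower at 6 h. Within plates the count was 1065, 680 higher and 385 lower. After row and column medians of columns 1 to 22 were also removed it was 537, 360 higher and 177 lower. Columns 23 and 24, which that removal left unchanged, held 275 of the 537. Columns 1 to 22 held 262, of which 225 were higher and 37 lower. The count depended on every sample. As deposited, it was 968 and 1552 without replicate 1 and replicate 2 at 1 h, and 216 and 563 without replicate 1 and replicate 2 at 6 h. Within plates it was 41, 97, 611 and 634 in the same order. With normal scores of the ranks as the scale, 961 wells were higher and 1260 lower at 6 h. That scale gives every sample the same symmetric distribution, so the larger direction depends on the scale.

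Within plates and over columns 1 to 22, 688 of 17944 wells differed between times, 517 higher and 171 lower at 6 h. Without replicate 1 or replicate 2 at 1 h, 11 and 42 wells differed, and without replicate 1 or replicate 2 at 6 h, 369 and 395. Of the 517, 160 were low at 1 h and not called at 6 h, 148 were high at 6 h and not called at 1 h, and 185 were called on the same side at both times. Of the 171, 93 were low at 6 h and not called at 1 h, and 55 were high at 1 h and not called at 6 h. Over all columns, the 5 largest rises and the 5 largest falls as deposited were all in columns 23 and 24. The largest rises by the ranking rule within columns 1 to 22 were on plate 21, in wells A04 and B01. The score of plate 21 well A04 was below its plate's median at both times, by -0.227 and -0.226 at 1 h and by -0.110 and -0.0618 at 6 h. Its z rose by 4.77 ± 0.335 (SE, limma adjusted p 0.00294), and by 4.49 within plates (adjusted p 0.0140). That of plate 21 well B01 rose by 4.41 ± 0.322 (SE, adjusted p 0.00294). Plate 21 as a whole spread less at 6 h. The SD over its columns 1 to 22 was 0.0451 and 0.0461 in the samples at 1 h, and 0.0355 and 0.0308 at 6 h. With each plate's own scale the rises were 2.95 for A04 and 2.69 for B01, with limma adjusted p-values of 0.0337 and 0.0177. The size of these rises thus depends on the spread of the plate. The largest falls within columns 1 to 22 were in plate 16 well P01, with a change of -2.81 ± 0.379 (SE), and plate 48 well B22, with -2.78 ± 0.379 (SE). Both had an adjusted p of 0.0117 as deposited, and of 0.0484 and 0.0409 within plates. Plate 16 well P01 is at the corner of the plate, and after row and column medians were removed its change was -1.87 with an adjusted p of 0.166.

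**Figure D2:**
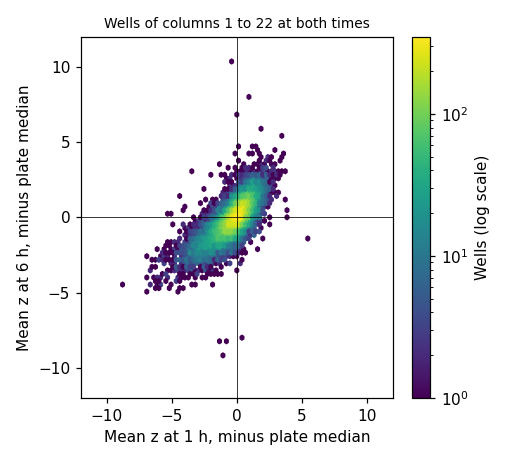
Mean z score at 1 h (horizontal axis) and at 6 h (vertical axis) of each well of columns 1 to 22, after subtraction of the plate median, with the number of wells in each hexagon on a log colour scale. Of the wells beyond 2 in both replicates at 1 h, 98.8% lie on the same side of 0 at 6 h, and 1003 of these 1126 wells are below 0.

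Columns 23 and 24 held wells that stood apart at the same positions across plates. The study states 2 control wells per plate without their positions, and none was assigned here. Positions are grouped by the values they showed, and values are scores minus the plate median, as means over 51 plates. The mean of wells G23 and O23 was above the plate median on 51 of 51 plates in each sample. It was 0.244 ± 0.131 and 0.249 ± 0.104 (SD over plates) in the samples at 1 h, and 0.384 ± 0.110 and 0.370 ± 0.116 at 6 h. Well B24 was at 0.0721 ± 0.0273 and 0.0767 ± 0.0313 at 1 h and at 0.164 ± 0.0813 and 0.168 ± 0.0725 at 6 h. Well B23 was at -0.130 ± 0.0892 and -0.115 ± 0.0889 at 1 h and at -0.0922 ± 0.0626 and -0.0831 ± 0.0745 at 6 h. Wells A23, A24, I23 and I24 had a mean of -0.0525 at 1 h, and lay below the plate median on 51 of 51 plates in both samples. At 6 h their mean was -0.0290. Wells C23 and K23 were near the plate median at 1 h, with a mean of 0.00578, and above it at 6 h, with a mean of 0.0651. Wells E23 and M23 had means of -0.00546 and 0.0115. The 20 remaining positions had a mean of 0.0463 at 1 h, above the plate median on 51 of 51 plates in both samples, and of 0.00923 at 6 h.

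Wells B23 and B24 set some plates apart. B23 lay more than 0.05 below the plate median in all 4 samples on 37 plates, and in no sample on 8 plates, which were plates 1 to 5 and 13 to 15. B24 lay more than 0.1 above the plate median in both samples at 6 h on 43 plates. These included all 37 plates with a low B23 and none of the 8 without.

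The edge of the plate was lower at 6 h and not at 1 h. Wells of columns 1 to 22 in row A, row P or column 1, 58 per plate, were compared with the 294 others. Their mean was higher by 0.00454 ± 0.00670 (SD over plates) and 0.00564 ± 0.00710 in the samples at 1 h. At 6 h the difference, edge minus others, was -0.0150 ± 0.0115 and -0.0160 ± 0.00845, and negative on 47 and 49 of 51 plates.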

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

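All differences between times at single positions, and the tests of explanations here, were chosen after the values were seen. The positions of columns 23 and 24 came up because their distance from the plate median changed between 1 h and 6 h. In a limma fit over the means of all positions of the plate, 31 of the 32 positions changed at an adjusted p under 0.05, 11 upward and 20 downward. The exception was A24, with a change of 0.00303 and an adjusted p of 0.348. That fit shares an estimate of spread over all positions, with an SE of 0.00277 to 0.00424 for these 32. Its p-values therefore do not measure how far 2 samples per time vary. The distance of G23 and O23 rose by 0.131 ± 0.134 (SD over plates), on 44 of 51 plates. That of B24 rose by 0.0917 ± 0.0673, on 43 of 51 plates, and that of C23 and K23 by 0.0593 ± 0.0331, on 49. B23 moved by 0.0344 ± 0.0484, upward on 43 of 51 plates. The mean of A23, A24, I23 and I24 moved by 0.0235 ± 0.0203, and that of E23 and M23 by 0.0169 ± 0.0215. The mean of the 20 remaining positions moved by -0.0371 ± 0.0168, down on 51 of 51 plates. What these positions received is not given in the sources used here, and no explanation was tested.

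The edge of the plate came up because its difference from the other wells of columns 1 to 22 changed by -0.0206 ± 0.00836 (SD over plates) between 1 h and 6 h, downward on 51 of 51 plates. The 688 wells of columns 1 to 22 that differed between times within plates were set against this. Of the 171 wells lower at 6 h, 76.0% lay in row A, row P or column 1, which hold 16.5% of these columns' wells. In the 130 such wells at the edge, the mean difference in z was -2.01 ± 0.393 (SD over wells) within plates and -1.01 ± 0.517 on the same scale after row and column medians were removed. In the 41 others it was -1.87 ± 0.360 and -1.52 ± 0.511. The share at the edge follows from the fall of the edge and tests nothing by itself. Of the mean difference of all 171, 57.4% was kept on the same scale, so the position at the edge may account for part of these calls and how much stays open. Without replicate 1 or replicate 2 at 6 h, 64.9% of 94 and 65.0% of 100 lower wells lay at the edge. Without replicate 1 or replicate 2 at 1 h too few were called to judge this, 2 and 11, of which 0 and 5 lay at the edge. Of the 517 wells higher at 6 h, 10.6% lay at the edge. Their mean difference was 2.16 ± 0.579 before and 1.85 ± 0.752 on the same scale after removal of row and column medians. The edge fell at 6 h, the direction opposite to these wells, so the 85.8% that was kept is no test of the edge. It argues against row and column medians as the whole source of these differences. It does not separate the differences from noise in the samples. Leaving out each sample in turn left 9, 31, 275 and 295 higher wells, so their number is not settled.

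Of all 688 wells, 201 (29.2%) were called again after that removal, and of the 462 higher wells away from the edge, 145 (31.4%). In these 462 the mean difference went from 2.15 ± 0.569 to 1.78 ± 0.706 on the same scale, and the largest raw p that passed the adjustment over all wells fell from 0.00272 to 0.00137. Calls there ended with a smaller difference and a stricter limit together, so the share called again was not used as a test of the edge. No biological explanation of the higher wells was tested, since wells cannot be tied to genes.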

How the results depend on the processing

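Settings that subtract or use plate medians, use columns 1 to 22 alone or leave out plates were chosen after the data were seen. The correlation of replicates stayed positive in the alternatives run for it (running, plate, row and column medians, each plate's own scale, columns 1 to 22, and plates left out), from 0.857 to 0.885 at 1 h and from 0.766 to 0.881 at 6 h. Counts of wells shifted at 1 h and 6 h, and their overlap, stayed within 1.5 times the reported counts, except under other size thresholds. On a common scale, 4615 wells were shifted at 1 h and 6980 at 6 h. With no size threshold the counts were 9747 and 9801, and with a size of at least 2 they were 1251 and 727. At 1 h, 2648 wells were higher and 3231 lower as reported, and 2947 were higher and 2900 lower with normal scores. Normal scores give every sample the same symmetric distribution, which by itself brings these 2 counts together. They are therefore no test of the larger direction at 1 h. Wells that differ between times, 2545 as reported, numbered 958 after subtraction of a running median, 1065 after subtraction of the plate median, 1036 with each plate's own scale, 537 after row and column medians were removed, and 1473 within plates without the 7 plates of low replicate agreement. Leaving out each sample in turn gave 216 to 1552 as deposited, and 41 to 634 within plates, where the count after row and column medians was also 537. Fewer samples leave a group with 1 sample and 1 residual degree of freedom, with the lone sample assumed to vary like the others. The higher wells were 56.3% of these calls as reported, 43.3% with normal scores and 67.0% after row and column medians were removed. Over columns 1 to 22, the only ones that this removal corrects, they were 62.6% as deposited and 85.9% after it. Wells beyond 2 in both replicates, 941 at 1 h and 487 at 6 h, numbered 1953 and 1382 at a threshold of 1.5 and 311 and 150 at 3. At 1 h they numbered 662 on a common scale, 553 with normal scores, 1485 with each plate's own scale and 1652 after row and column medians. At 6 h they numbered 759 on a common scale, 1049 after a running median, 1079 after the plate median, 943 with each plate's own scale, 1427 after row and column medians, 319 over columns 1 to 22 alone, and 971 within plates without the 7 plates. The higher wells among them at 1 h were 17.2% as reported, 41.0% with normal scores, 29.7% after row and column medians and 5.60% over columns 1 to 22 alone. At 6 h they were 56.1% as reported, 46.0% with log2, 42.9% after a running median, 42.4% after the plate median, 44.2% with each plate's own scale, 43.8% after row and column medians and 39.8% over columns 1 to 22 alone, so their larger direction changed. Normal scores also make the 2 sides of each sample alike. The cause of the other changes was not tested. Named wells kept their sign in all alternatives run, and their calls in 44 of 44 at 1 h, 35 of 44 at 6 h (all but those of plate 25 wells F21 and H20 after running or plate medians, with or without rescaling or row and column medians, and of plate 51 well H05 after row and column medians) and 43 of 44 for the contrast (all but plate 16 well P01 after row and column medians). Not run for want of gene names were the gene lists with their alternatives, sensory receptor genes as the reference, and other rules for several values of a gene. No paired analysis was possible because the labels pair no sample at 1 h with one at 6 h. The number of cells behind each score is not given in the sources used here, so its limit on precision is unknown.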

Other observations

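All tests in this part were chosen after the values they concern were seen. In columns 1 to 22, replicates shared less spread on plates 11 to 19 than on the others. The spread that replicates share, the square root of their covariance over these columns, had a median of 0.0227 on these 9 plates and 0.0393 on the other 42 at 1 h, and of 0.0245 and 0.0383 at 6 h. By this measure, plates 11 to 19 were 8 of the 9 narrowest plates at 1 h and 9 of 9 at 6 h. The scores themselves did not spread less on plates 13 to 15 at 6 h. Their SD per sample was 0.0374 to 0.0443, and the medians over plates other than 25 were 0.0409 and 0.0408. The small shared spread of these 3 plates at 6 h rests on the low correlation of their replicates, given below. Plates 11 to 19 held 47 of the 1126 wells beyond 2 in both replicates at 1 h within plates, or 5.22 per plate against 25.7. At 6 h they held 41 of 870, or 4.56 per plate against 19.7. These z scores use 1 scale per sample, so a smaller shared spread by itself lowers the counts, and they are no separate evidence. Weaker transfection or a weaker response of whole plates would shrink the distance of G23 and O23 from the plate median if these wells hold active siRNA. The median of that distance from the plate median, as a mean of the 4 samples, was 0.399 on plates 11 to 19 and 0.278 on the other plates, whose 5th percentile was 0.205. It was not smaller on plates 11 to 19. Well B23 goes the other way, being more than 0.05 below the plate median in all 4 samples on 3 of these 9 plates and on 34 of the other 42. But B23 was low in no sample on plates 1 to 5 either, whose shared spread at 1 h was 0.0359 to 0.0416. B24 was high at 6 h on 6 of the 6 plates 11, 12 and 16 to 19, and on 0 of plates 13 to 15. A B23 that is not low thus does not by itself go with a narrow spread. What these wells received is not given in the sources used here, so this explanation stays open. A compression by low scores is argued against at 1 h. Over the other 42 plates, the correlation of shared spread with plate median was -0.312 at 1 h and 0.0695 at 6 h. At 6 h, though, plates 11, 12 and 16 to 18 mostly lay below the range of those plates. In replicate 2 their medians were 0.953 to 0.964, against a lowest of 0.978 (plate 33) on the other 42. The correlation therefore cannot decide for them at 6 h. Plates 13 to 15 and 19 had a small shared spread at 6 h with medians of 1.03 to 1.10, so low scores do not account for them. A different set of genes on these plates may give a narrower spread, but this stays open and was not tested, since the files name no genes.

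The change of G23 and O23 between times also differed by plate. On plates 11 to 19 their distance was 0.372 at 1 h and 0.432 at 6 h, and rose on 4 of 9 plates. On the other plates it was 0.219 and 0.365, and rose on 40 of 42. The difference between these sets of plates was not tested.

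Plates 13 to 15 were 3 of the 4 plates with the lowest correlation between replicates at each time, beside plate 44 at 1 h (0.519) and plate 25 at 6 h (0.424). Over columns 1 to 22 their correlation was 0.474 to 0.626 at 1 h and 0.395 to 0.443 at 6 h, where the other plates had medians of 0.892 and 0.835. Their values were set against the 42 plates outside 11 to 19. At 6 h the shared spread was 0.0254 to 0.0280. The lowest of the 42 plates was also at 0.0280 (plate 21), so only plate 14, at 0.0254, lay clearly below it. The shared spread of plates 13 to 15 was not below the 0.0187 to 0.0265 of plates 11, 12 and 16 to 19, whose correlations were 0.579 to 0.865. The SD of the replicate difference was 0.0445 to 0.0452, above the 95th percentile of the 42 plates (0.0335) on 3 of 3 plates and above the 0.0149 to 0.0227 of those 6 neighbours, though larger still on plate 25 (0.0734) and plate 51 (0.0591). The narrower spread with a replicate difference at that 95th percentile would give correlations of 0.535 to 0.582, above those observed, which argues against a narrower spread alone at 6 h. The larger difference with a spread at the 5th percentile (0.0310) would give 0.484 to 0.492. This lies above the observed values by 1.19 to 2.14 errors of Fisher's z, so larger noise alone stays open at 6 h, as do both together. Against the 6 neighbours, the replicate difference and not the spread set plates 13 to 15 apart at 6 h. At 1 h the shared spread was 0.0175 to 0.0221, and the SD of the replicate difference, 0.0233 to 0.0263, was above the 95th percentile (0.0270) on 0 of 3 plates. Larger noise alone, with a spread at the 5th percentile, would give 0.747 to 0.791, which argues against it. The narrower spread, with noise at the 95th percentile, would give 0.457 to 0.572, within 2 errors of the observed values or below them. But the 6 neighbours, with spreads of 0.0226 to 0.0294, had correlations of 0.654 to 0.882, and with their median replicate difference (0.0167) plates 13 to 15 would have 0.689 to 0.779, above those observed. Plates 13 and 14 were narrower than all 6, while plate 15, at 0.0221, was close to plates 11 and 12. A narrower spread alone therefore stays open at 1 h.

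Poor transfection of plates 13 to 15 stays open for the same reason as on plates 11 to 19, and the fixed positions differ. The distance of G23 and O23 from the plate median was 0.425 to 0.432, above the median of 0.289 on the other plates. B23 was low in no sample and B24 high at 6 h on 0 of these 3 plates, where 34 and 37 of the 42 plates outside 11 to 19 had a low B23 in all samples and a high B24. What any of these wells received is not given in the sources used here. No biological explanation was tested.

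Most missing scores were on 2 plates. All 3 wells without a score in replicate 1 at 6 h were on plate 51 in column 23, and 6 of the 7 in replicate 2 at 6 h were on plate 25. The others were plate 41 well B10 in that sample and plate 14 well H10 in replicate 1 at 1 h.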
